A study of Danio rerio with 4 samples.

How the data were processed

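RNA was measured in 4 libraries of whole zebrafish larvae from crosses between carriers of a znf574 mutation. Per the labels, 2 libraries came from znf574 mutant larvae and 2 from siblings of wild-type appearance, which were homozygous wild type or heterozygous. The 2 groups are called mutant and wild type, or the genotypes, below, although the sibling group may hold both of its genotypes. The larvae were sorted by appearance 7 days after fertilization. The labels state neither how many larvae went into a library nor whether the replicates came from separate clutches, so the p-values measure the spread between these libraries, which may be partly technical. Per the labels' protocols, RNA was extracted with phenol and chloroform and libraries were made with a stranded poly(A) mRNA kit.

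Per the submitters' processing notes, base calls were converted with bcl2fastq 2.20 and transcripts were quantified with kallisto 0.46.0, a program that assigns reads to transcripts without a full alignment. The notes also name DESeq2 2.11.40 and the builds GRCz11 and danRer11. The annotation release and the kallisto options are not given in the sources used here. Each deposited table lists 57775 transcripts by Ensembl transcript identifier with a length, an effective length, an estimated count and a TPM value. The estimated counts deposited by the authors are not normalized, and reads that match several transcripts are divided among them by kallisto's model, so they need not be whole. The TPM values deposited by the authors are estimated counts divided by effective length and scaled to 1000000 per library. In all 4 tables the effective lengths were identical, and for 99.8% of transcripts they were the length minus 50 bases. A correction for transcript length that differs between libraries therefore had nothing to act on and was not run.

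The files do not pair transcripts with genes. The name table used here holds 29201 gene identifiers, and 0 of the transcript identifiers matched it. The comparison was therefore made per transcript, as foreseen in the design. Sums per gene, the level of znf574 itself, the 39 pathway and cell type lists written beforehand, and the count of changed genes on the chromosome of znf574 were not analysed here. For the same reason the labels could not be checked against the mutated gene, and no gene functions or coordinates are given. Transcripts of 1 gene share reads, and the deposited tables used here carry no estimate of that uncertainty.

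Estimated counts were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. The settings were filterByExpr (minimum count 10, minimum total count 15), TMM normalization, robust estimation and the non-legacy quasi-likelihood fit, with group as the only term. A transcript was called changed at a Benjamini-Hochberg adjusted p under 0.05. The filter left 39773 transcripts, and those removed held at most 0.281% of the counts of any library. CPM values are counts per 1000000 of the TMM-adjusted library size. The total of estimated counts ranged from 31653921 to 42901442 per library. At these depths 3 counts, taken as the limit that a count of 0 allows, equal 0.0674 to 0.0922 CPM. Such limits and the exact binomial intervals given for shares cover counting error only, and transcripts are not independent of each other.

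The rule fixed for naming was the 12 largest rises and 12 largest falls among changed genes with an assigned symbol, a mean log2 CPM of at least 2 and no overlap between groups. With no symbols, only the first 2 transcripts in each direction are named, without the condition on symbols. The replicate numbers in the titles are shared by both groups, but no label ties them to a clutch or day. Across transcripts, the deviations of same-numbered libraries from their group means correlated at -0.122, so the numbers were not taken as pairs.

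The test was tried on simulated counts for the mutant against wild-type comparison, with the real means, library sizes and dispersion trend. Every transcript was drawn at the trend, without the spread around it that real transcripts have. Changes were planted in 200 transcripts with a mean of at least 50 counts, and 37832 transcripts passed the filter. The test recovered 1 of 64 planted changes of 1 on the log2 scale. It recovered 38 of 70 changes of 2 and 52 of 66 changes of 3, with 4 false calls. With a low dispersion of 0.01 it recovered 196 of the 200, with 12 false calls among 38730 transcripts. The shares recovered hold for 200 changes in this setting. Neither they nor the false calls measure the error rates of the test on the real counts. With more changed transcripts the adjustment is less strict. Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE, upper quartile and plain library size scaling, no filter and a filter of 1 CPM in all 4 libraries, limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1), the legacy quasi-likelihood fit, leaving out the 50 most abundant transcripts, a minimum absolute log2 fold change of 1, the replicate number as a block, and leaving out each library. Alternatives chosen after the data were seen were a crossed block, transcripts with whole estimated counts only, an offset for each library's trend with transcript length, and DESeq2 with each library left out or with the block, and the legacy fit without each wild-type library. Figures were drawn with matplotlib 3.10.9.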

Results

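Poly(A) RNA of whole zebrafish larvae was sequenced to find transcripts that differ between znf574 mutant larvae and their siblings. The series describes znf574, a zinc finger gene, as acting in quality control of ribosome assembly. Mutant larvae and their siblings of wild-type appearance were each represented by 2 libraries. The wild-type sibling libraries held 35764394 and 36320540 estimated counts, and the mutant libraries held 42901442 and 31653921. Of the 57775 transcripts listed, 44507 and 44281 had an estimate above 0 in the wild-type libraries, and 45216 and 45303 in the mutant libraries. The transcripts are known here by identifier only, so the results below describe transcripts and classes of transcripts, not genes or pathways, and the level of znf574 was not analysed here.

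The libraries of 1 genotype resembled each other more than those of the other. Across the 39773 tested transcripts, which are not independent replicates, the Pearson correlation of log2 CPM was 0.91 between the wild-type libraries and 0.88 between the mutant libraries. It ranged from 0.73 to 0.78 for the 4 pairs of a wild-type and a mutant library. The median absolute log2 ratio of a transcript was 0.29 between the wild-type libraries, 0.32 between the mutant libraries and 0.67 to 0.79 between genotypes. The first principal component held 65.7% of the variance and separated the genotypes. The second, with 20.2%, separated mutant replicate 1 from mutant replicate 2, with the wild-type libraries between them. As a check for repeat deposits of 1 library, the counts of the wild-type pair differed with a chi-square of 54.9 per transcript and those of the mutant pair with 106, where a repeat of the same library would give about 1 or less.

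The comparison asked which transcripts differ between mutant larvae and wild-type siblings. Whole larvae sorted by appearance were used. Changes in RNA level within cells therefore cannot be told apart from differences in tissue make-up or health between the groups. In mutant larvae 3779 transcripts were higher and 4069 lower, together 19.7% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 2 libraries per group). The median change was 1.51 on the log2 scale among transcripts that rose, or 2.85-fold, and -1.45 among those that fell, or 2.73-fold. Of these, 344 rising and 365 falling transcripts were at 0 in both libraries of the other group, and the medians include them; with each set to the limit that a count of 0 allows, the medians are 1.51 and -1.45. A change of at least 8-fold was reached by 749 of the transcripts that rose and 936 of those that fell. An approximate SE, the absolute log2 fold change divided by the square root of the F statistic, had a median of 0.34 over all tested transcripts. For transcripts at 0 in 1 group this value depends on edgeR's prior count and is no measured spread. The transcripts that rose took 7.59% and 6.82% of the counts in the wild-type libraries and 20.5% and 19.1% in the mutant libraries. Those that fell took 27.9% and 28.0% of the counts in the wild-type libraries and 12.6% and 12.4% in the mutant libraries.

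The edgeR calls rested on having both wild-type libraries and on fitting no replicate block. With the replicate number as a block and all 4 libraries, edgeR called 0 transcripts. Without wild-type replicate 1 or without wild-type replicate 2 edgeR called 0 transcripts, with 10695 and 10424 at an unadjusted p under 0.05, while DESeq2 called 4761 and 4653. Without mutant replicate 1 edgeR called 3884 transcripts, and without mutant replicate 2 it called 7448. In each of these fits the genotype with 1 library was assumed to vary like the other. Whether more transcripts rose or fell depended on the scaling: 48.2% of the calls were higher in mutants with TMM, 52.3% with upper quartile scaling, 55.4% with library size alone and 58.1% with limma on log2(TPM + 1). The fold change of a transcript shifted upward from the TMM fit by a median of 0.10 on the log2 scale with library size alone and of 0.16 with limma on log2(TPM + 1), which changes the scale, the pseudocount and the model together.

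**Figure D1:**
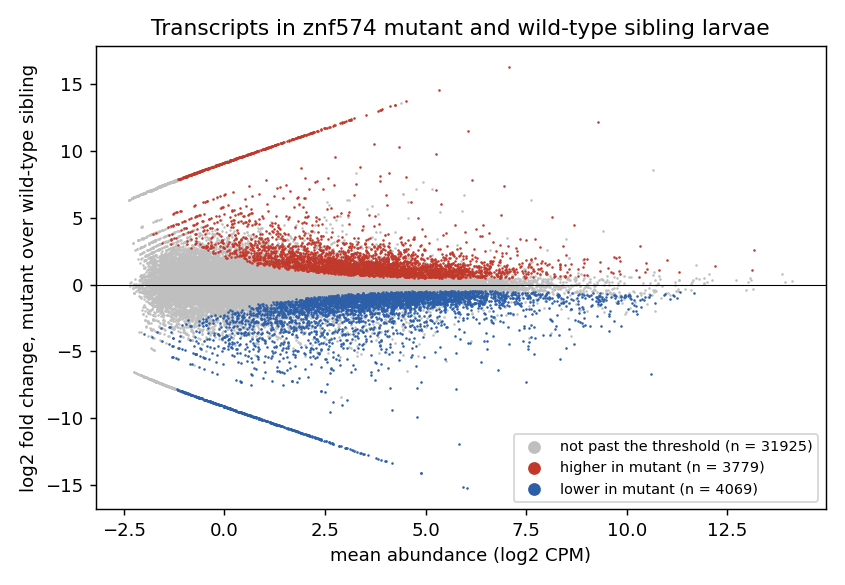
Each point is 1 of the 39773 tested transcripts, with its mean abundance in log2 CPM on the x axis and its log2 fold change of mutant over wild-type sibling larvae on the y axis. Red points are the 3779 transcripts that were higher in mutants and blue points the 4069 that were lower (edgeR, adjusted p under 0.05). The straight outer bands are transcripts at 0 in both libraries of 1 group, whose plotted fold change depends on edgeR's prior count and is no measured size.

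Abundant transcripts fell more often than they rose. Of 1106 transcripts with a mean of 100 to 1000 CPM, 292 were lower in mutants and 159 higher, so that 35.3% of the calls were rises (95% exact binomial interval 30.8 to 39.9%). Of 117 transcripts at 1000 CPM or more, 32 were lower and 12 higher. Among transcripts of 10 to 100 CPM, 1885 fell and 1636 rose, and among those of 1 to 10 CPM the numbers were 1625 and 1693. Below 1 CPM, 235 transcripts fell and 279 rose out of 8746 tested. The larger number of falls among transcripts of at least 100 CPM, 324 against 171 with TMM, held under every scaling that was tried, with 286 against 188 for library size alone and 205 against 163 for limma on log2(TPM + 1). Without mutant replicate 1 it was 189 against 116, and without either wild-type library edgeR called none.

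Short transcripts also fell more often than they rose. Of 1414 transcripts of up to 500 bases, 135 were lower in mutants and 51 higher. Of 8424 transcripts of 501 to 1000 bases, 790 were lower and 384 higher, so that 32.7% of the calls were rises (95% exact binomial interval 30.0 to 35.5%). Between 1001 and 2000 bases 1227 transcripts fell and 1122 rose. Between 2001 and 4000 bases 1248 fell and 1430 rose, and above 4000 bases 669 fell and 792 rose. The median log2 fold change of all tested transcripts went from -0.43 at up to 500 bases to 0.07 above 4000 bases. The excess of falls among transcripts of up to 1000 bases, 925 against 435, held under every scaling that was tried, with 800 against 476 for library size alone and 1089 against 865 for limma on log2(TPM + 1). It was 519 against 215 without mutant replicate 1, and without either wild-type library edgeR called none. It narrowed to 726 against 573 when each library's trend with length was removed. The excess of rises above 2000 bases, 2222 against 1917, turned to 935 against 1103 without mutant replicate 1 and to 1914 against 2308 when each library's trend with length was removed. Length was also related to the ratio of the mutant libraries to each other: its Spearman correlation across transcripts with the log ratio of replicate 2 to replicate 1 was -0.13 in mutants and -0.02 in wild type, against 0.07 to 0.13 for mutant over wild-type library.

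**Figure D2:**
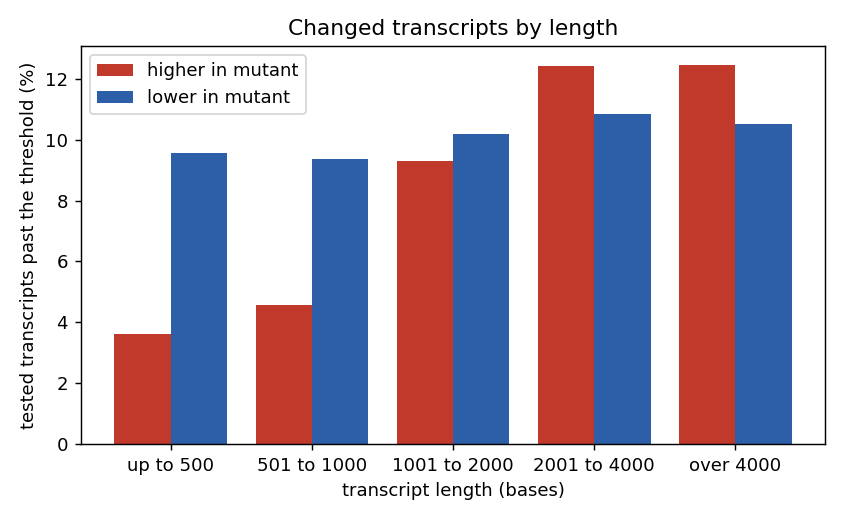
The x axis groups the tested transcripts by length in bases, and bars give the percentage of each group that was higher (red) or lower (blue) in mutant larvae at an adjusted p under 0.05 in edgeR. Rises went from 3.61% of transcripts of up to 500 bases to 12.5% of those above 4000 bases, while falls stayed between 9.38% and 10.8%.

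Some transcripts were present in 1 genotype and at 0 in the other. At least 10 counts in both mutant libraries and 0 in both wild-type libraries were found for 714 transcripts, with a median of 1.199 CPM in mutants. The edgeR test called 344 of these 714 changed. The reverse pattern was found for 642 transcripts, with a median of 1.61 CPM in wild type, and 365 of these 642 were called. Pairing wild-type replicate 1 with mutant replicate 1 against the other 2 libraries gave 234 such transcripts in both directions together, and pairing it with mutant replicate 2 gave 307, against 1356 for the genotypes. Nearly all of them had estimated counts that were not whole, so that at least some of their reads were divided with other transcripts. The deposited estimates do not show what share of a transcript's reads was divided. Among transcripts with whole estimates in both mutant libraries, to within 0.005 and below 10000 counts, 3 of 5967 were at 0 in both wild-type libraries, or 0.0503%, against 710 of 28404 with divided estimates, or 2.50%. In the other direction it was 5 of 6110, or 0.0818%, against 637 of 27940, or 2.28%.

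The transcripts with the largest fitted fold changes in either direction belonged to this class. ENSDART00000183657.1, of 1950 bases, was at 268 ± 57.7 CPM in mutants (SD, n = 2) and at 0 counts in both wild-type libraries, at least 3099-fold higher against a limit of 3 counts per library (edgeR adjusted p = 0.0083). ENSDART00000146994.4, of 5219 bases, was at 80.1 ± 25.7 CPM in mutants (SD, n = 2) and at 0 in wild type after rounding, at least 928-fold higher (edgeR adjusted p = 0.012). ENSDART00000188371.1, of 1221 bases, was at 130.3 ± 14.6 CPM in wild type (SD, n = 2) and at 0 in both mutant libraries, at least 1632-fold lower in mutants (edgeR adjusted p = 0.0082). ENSDART00000171828.2, of 582 bases, was at 123 ± 11.9 CPM in wild type (SD, n = 2) and at 0 in both mutant libraries, at least 1536-fold lower (edgeR adjusted p = 0.0082). None of the 4 had a whole estimated count in a library where it was detected. The fold limits above cover counting error only. They are no lower bounds if kallisto assigned reads of these transcripts to others. Without wild-type replicate 1 the edgeR adjusted p was 0.10 for each of the 4, and without wild-type replicate 2 it was 0.11. The fitted log2 fold changes, which depend on the prior count, were 16.26, 14.52, -15.22 and -15.13 with all libraries. They were 16.26, 14.52, -15.34 and -15.24 without wild-type replicate 1, and 16.31, 14.57, -15.13 and -15.06 without wild-type replicate 2. Leaving out any 1 library took the residual degrees of freedom from 2 to 1. Without a mutant library these transcripts stayed past the threshold, so that loss alone does not explain the higher adjusted p. The cause was not tested. Over the 24 alternatives in which they were tested, the adjusted p of each (edgeR, DESeq2 or limma) reached 0.14 at most and missed the threshold in 5.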

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

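With 2 libraries per group, leaving out 1 library moved the rises between 0 and 3409 and the falls between 0 and 4039. Both counts were 0 without either wild-type library, in the legacy fit too (10215 and 9895 transcripts at an unadjusted p under 0.05), and 1610 and 2274 without mutant replicate 1. DESeq2, which called 5479 rises and 5754 falls with all 4 libraries, was run on the reduced sets after the data were seen. It called 2614 rises and 2147 falls without wild-type replicate 1, 2618 and 2035 without wild-type replicate 2, 1841 and 3534 without mutant replicate 1, and 5715 and 7662 without mutant replicate 2. With the replicate number as a block, which the labels do not tie to a clutch or day, edgeR called 0 rises and 0 falls, with 12361 transcripts at an unadjusted p under 0.05 and 1 residual degree of freedom, whereas DESeq2 with the same block called 6107 and 6545; the cause was not tested. A crossed block gave 2779 and 3120. In limma on log2(TPM + 0.1) the falls dropped to 2410, and the cause was not tested. Transcripts with whole estimated counts gave 578 rises and 649 falls because only 5663 were tested. Under DESeq2 with all 4 libraries, RLE, upper quartile, library size, both filters, limma on log2(TPM + 1), the legacy fit, the fit without the 50 most abundant transcripts, the minimum fold change and the length-trend offset, both counts stayed within 1.5 times of 3779 and 4069. Of the DESeq2 calls, 3773 of the rises and 4056 of the falls were shared with edgeR. With the length-trend offset, the excess of rises above 2000 bases turned to 1914 against 2308. The 4 named transcripts, at 0 in 1 group, could not change direction, and they were not tested under the filter of 1 CPM in all 4 libraries or among whole counts. A tximport-like offset from the deposited effective lengths, which is another correction than the length-trend offset, sums per gene, the gene lists and the chromosome count were not run, for want of effective lengths that differ between libraries and of a pairing of transcripts with genes. Depth leaves levels under 3 counts, or 0.0674 to 0.0922 CPM, unresolved; of transcripts under 1 CPM 5.88% were called, and whether depth sets that share was not tested.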

Other observations

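The tests of depth and of other splits of the libraries were chosen after their results had been seen. The tests on length, with the length-trend offset as an added alternative, and the test on divided reads were chosen after the counts by length and the transcripts at 0 had been seen, but before their own results.

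The tables argue against reading each transcript at 0 in 1 genotype as a gene switched on or off: transcripts with whole estimates were at 0 in the other genotype far less often than divided ones of like abundance, with a Mantel-Haenszel odds ratio of 0.0297 (95% interval 0.0148 to 0.0595). A candidate explanation is that kallisto moved the reads of a gene between near-identical transcripts, such as alternative isoforms or allelic copies that differ in few bases. The split by group held more such transcripts than the other pairings of libraries, 1356 against 234 and 307. So few pairings cannot show that a shift follows genotype rather than another difference shared by the libraries of a group. A difference in splicing or in the haplotypes carried by mutants stays open and untested. Heterozygous siblings also carry a mutant haplotype, but the labels do not state how many larvae went into a library. Sequences and gene assignments for these transcripts would be needed to tell splicing from haplotypes.

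The lower level of short transcripts in mutants may come from a technical length bias between libraries. The difference in median log2 fold change between transcripts above 2000 bases and those of up to 1000 bases was 0.45 among the least abundant transcripts, 0.50 among those of middle abundance and 0.42 among the most abundant, when the tested transcripts were cut into 3 equal groups by abundance, as a bias acting on all transcripts would give. The rank correlation of length with the ratio of the mutant libraries to each other had a size of 0.13, above the smallest value between genotypes, 0.07. For the wild-type pair it was -0.02, smaller in size than every value between genotypes, 0.07 to 0.13. Removing each library's trend with length, which takes part of the pattern away by construction, left 726 falls against 573 rises up to 1000 bases, from 925 against 435. A difference in RNA integrity between larvae of the 2 genotypes, and an effect of the mutation on short transcripts, both stay open. A smooth trend with length does not account for the number of changed transcripts. With each library's length trend removed, 7876 were called, 7205 of them shared in direction with the 7848 called without the correction. A large drop was unlikely from the start, since medians by length class ran only from -0.43 to 0.09. The transcripts called had median changes of 1.51 and -1.45. Other forms of length bias were not tested.

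Both mutant libraries held more transcripts with at least 10 counts than either wild-type library, 38345 and 37672 against 37477 and 37123. With all libraries thinned to 31653855 counts in 20 draws, the means were 36884 and 37672 in mutants and 36927 and 36470 in wild type. Depth fits for mutant replicate 1, the deepest library, which then lay -42.8 transcripts from the higher wild-type library and still above the other. It is excluded for mutant replicate 2 by the values as deposited, since this shallowest library held 195 more such transcripts than the higher of the deeper wild-type libraries. Thinning left that library unchanged and lowered the wild-type libraries, so it could only widen the gap and adds no separate test. No other explanation was tested.

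The 4 libraries allow only 3 splits into pairs, too few for a share under 0.05. The real split was the 1 split with as many as 7848 changed transcripts, and the highest of the others gave 0 (371 and 586 transcripts at an unadjusted p under 0.05, edgeR). Each of the others put both genotypes into each group, so any difference between genotypes widened the spread within groups. Their counts therefore do not show how many calls to expect without a difference, and no conclusion is drawn from them.

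Transcripts with whole estimated counts in all 4 libraries, whose reads were not divided, were called at 20.6%, and all others at 19.6%. Counts were more concentrated in the mutant libraries. The 10 largest transcripts of each library, which need not be the same ones, held 8.47% and 9.95% of the counts in wild type and 12.02% and 14.57% in mutants.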
